A study of Mus musculus with 25 samples.

How the data were processed

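The samples are total RNA from brain hemispheres of 25 male C57BL/6 mice, 5 each at 2, 9, 15, 24 and 30 months of age. Per the submitters' processing notes, the authors called bases with CASAVA 1.7, aligned reads with STAR 2.4.1d to GRCm38 and made the counts per Ensembl gene with featureCounts 1.4.6-p4; the table of counts was deposited without further normalization. The annotation release and the counting settings are not stated. The authors also deposited RPKM values, that is reads per kilobase of gene length and per 1 000 000 counts, computed from those counts. Of the cells of the deposited RPKM values, 4% were found to be divided by the total of their own library. The others are divided by the total of another library, by a factor of 0.569 to 1.76 from their own, because the totals run down the genes and not along the libraries. The counts are therefore the basis of all comparisons, and the RPKM values serve as alternatives only. Replicate numbers follow the order of the samples in the series. They pair no animals across ages, so no paired analysis was made.

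The table holds 47729 genes, of which 47310 match the GENCODE M21 annotation of GRCm38 by Ensembl identifier and 419 do not. Symbols, coordinates, gene types, lengths and the GC content of the longest transcript come from that annotation. Library totals were 17.8 to 31.3 in units of 1 000 000 counts. With 5 libraries per age the precision is set by the spread between libraries more than by depth. The chi-square per degree of freedom between replicates was 1.55 to 6.97 in pairs of the younger ages, where counting error alone gives 1. In pairs of 30 months it was 4.965 to 146. Whether this spread lies between animals or arises in library preparation was not tested.

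Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr, which left 17799 genes, and libraries were scaled with TMM. All 25 libraries entered 1 quasi-likelihood fit with robust dispersions and a mean per age. The pairs of ages compared in it were 9, 15, 24 and 30 with 2 months, 15 with 9, 24 with 15, 30 with 24 and 30 with 9 months. A further fit gave a linear trend in months, and the departure from that line was tested with 3 further terms. All p values of genes are two-sided and adjusted by Benjamini and Hochberg over the genes tested, at 0.05. Log2 fold changes give the older relative to the younger age, and levels are CPM (counts scaled to a total of 1 000 000) after TMM scaling, except in the depth and quality values of single libraries, which use total counts.

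44 gene lists with 710 listed genes were fixed in advance. They cover microglia, complement, antigen presentation, interferon response, lymphocytes, cytokines, lysosome, astrocytes, oligodendrocytes, neurons and synapses, immediate early genes, mitochondria, ribosomes, heat shock, senescence, circadian clock, glucocorticoid response, cholesterol synthesis, glycolysis, collagens, vessels, meninges, choroid plexus, ependyma, red blood cells, beta protocadherins and neighbouring regions. Lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01, adjusted over the lists. As alternatives camera was run with a correlation estimated per list, and fry was run. The p of fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. Counts adjusted over the list alone use the p values of the list's members only.

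The genes named in the text follow a rule. They are past an adjusted p of 0.05, their libraries do not overlap between the 2 ages, and their mean is at least 2 CPM over all libraries. Predicted gene models, pseudogenes and immunoglobulin or T cell receptor segments were left out. From these the 12 largest rises and 12 largest falls are named for 30 with 2 months, 6 and 6 for 9, 15 and 24 with 2 and for 30 with 9 months, and 4 and 4 for the other pairs. For 15 with 9 months 1 rise and 1 fall met the rule. For the trend the 10 rises and 10 falls with the smallest p are named, for the departure the 8 genes with the smallest p, and for each list up to 3 members by smallest p in 30 with 2 months. A few genes that the rule selects are left out of the text, and no others were taken in their place. Chance gives non-overlapping groups of 5 and 5 in 0.794% of genes. Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were read as checks of sex. These choices, the lists and the settings planned for comparison were made before the data were examined.

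Early and late changes were compared by the correlation across genes of the log2 fold changes of 9 with 2 and of 30 with 15 months. Its p comes from the exact permutation of the library labels. The overlap of 24 with 2 and 30 with 2 months, which share the 2 month libraries, was set against 20 simulations of unchanged groups and against 20 splits of the 2 month libraries into 2 and 3. Chance groupings of the libraries were counted over 100 drawn splits per result. Values far from their group were found with Dixon's ratio, with a limit of 0.71 for 5 samples.

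Other settings planned for comparison were RLE size factors, total counts alone, no filter beyond 1 count, and a stricter filter of 1 CPM in 5 libraries and a mean of 20 counts. Others were limma-voom, DESeq2 1.42.0, limma on log2 of the deposited RPKM with pseudocounts of 0.1 and 1, and 1 surrogate variable from sva 3.50.0. Fits with only the 2 ages compared, trends on log2 of months and on 9 to 30 months, and fits without each library in turn were planned as well. Settings chosen after seeing the data were a fit without replicates 2 to 5 of 30 months, a correction for GC content, and a correction for GC content and length. The corrections are offsets from splines with 6 degrees of freedom per library. A covariate of the mean log2 CPM of liver transcripts, RPKM recomputed with each library's own total, 24 with 15 months as the late pair, and the fit without the 4 libraries together with the GC correction were also chosen after seeing the data. Library GC trends were measured over 12807 protein-coding genes with a mean of at least 50 counts.

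The gene tests were tested on simulated data with planted changes in groups of 5. They recovered 83.6% to 89.6% of genes planted at 1.5-fold and 95.5% to 100% of those at 2-fold, with 3 to 12 false calls among 17799 genes. Changes were planted only in genes with a mean of at least 2 CPM, so recovery of less abundant genes was not measured. Planted lists were recovered in 4 of 4 cases with 0 calls among 40 others. Genes were drawn independently there, so this does not test lists whose genes vary together. A planted GC trend in 4 libraries gave 6253 false calls without and 5 with the GC correction. The planted trend followed the same GC content that the correction uses, so its removal was built in. It does not show how well the correction works on the real libraries. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.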

Results

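Gene expression was measured by RNA sequencing of total RNA from brain hemispheres of 25 male mice of the inbred strain C57BL/6. The animals fell into 5 age groups, 2, 9, 15, 24 and 30 months, with 5 animals and 5 libraries in each. The series compares the ages of the brain. Library totals, in units of 1 000 000 counts, ran from 17.8 to 31.3, with a mean of 23.6. They were 20.7, 19.7, 31.3, 17.8 and 19.9 in the 2 month libraries and 28.1, 24.2, 27.1, 21.8 and 21.9 in the 9 month libraries. The 15 month libraries held 18.6, 25.9, 24.7, 24.0 and 21.4 units, the 24 month libraries 28.9, 23.1, 28.6, 23.02 and 30.1, and the 30 month libraries 23.5, 19.8, 24.8, 20.6 and 19.9. After the filter on low counts, 17799 genes were tested, and all comparisons give the older group relative to the younger.

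Sex markers were as the label male requires in all 25 libraries. Xist, the RNA that coats an inactive X chromosome, had at most 17 counts in any library. The Y-linked Ddx3y, an RNA helicase, stood at 9.28 to 98.0 CPM (counts scaled to a library total of 1 000 000), Eif2s3y at 14.3 to 59.8, Kdm5d at 8.37 to 44.6 and Uty at 5.82 to 37.2. Replicates 2 to 5 of the 30 month group stood apart from the other 21 libraries. In these 4 libraries Ddx3y was at 9.28 to 17.9 CPM, against 70.9 in replicate 1 of the same age. Genes with high GC content read high and genes with low GC content read low in them. Over 12807 protein-coding genes, the median log2 ratio of the 10% with the highest GC content exceeded that of the 10% with the lowest by 1.04 to 1.95. The same gap was 0.07 in replicate 1 of 30 months and -0.30 to 0.08 in the 20 younger libraries. Mitochondrial ribosomal RNA took 1.40% to 1.89% of counts in all 5 libraries of 30 months and 0.633% to 0.847% in the younger ones. Counts of genes that involve 30 months, and the values of some lists and named genes, are therefore also given without these 4 libraries, an alternative chosen after the data were seen. It leaves 1 library at 30 months, which is assumed to vary like the other groups.

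**Figure D1:**
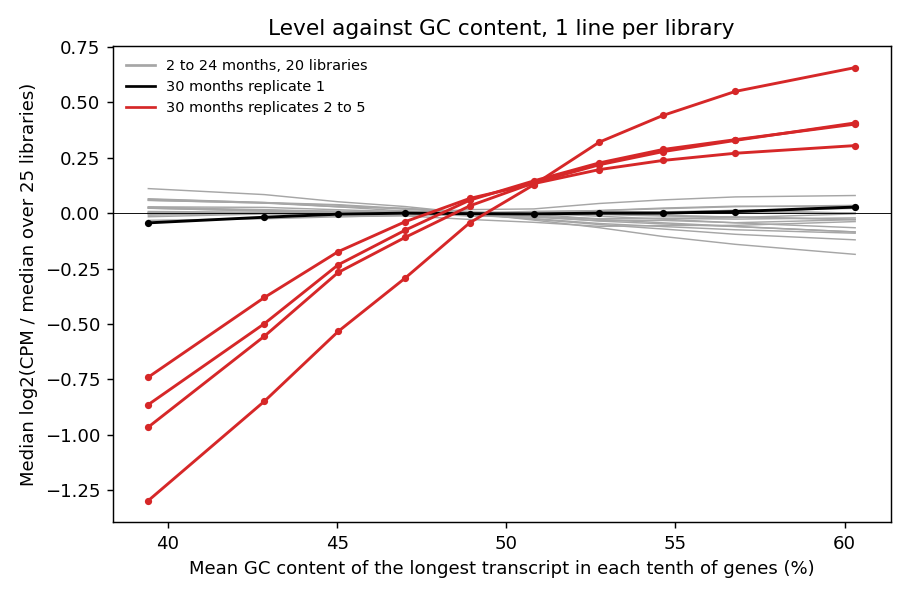
Median log2 ratio of CPM to the median of all libraries (y axis) in groups of 10% of genes ordered by GC content of the longest transcript in percent (x axis), 1 line per library. Replicates 2 to 5 of 30 months, in red, climb with GC content by 1.04 to 1.95 from the lowest to the highest group. In the other 21 libraries the same difference lies between -0.30 and 0.08.

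Transcripts of liver and of choroid plexus varied between libraries of the same age. Alb, the serum albumin made by liver, stood at 17.5 to 170 CPM in 13 libraries and at 0 to 7.60 in the others. Those 13 were 1 of 5 libraries at 2 months, 2 at 9, 4 at 15, all 5 at 24 and 1 at 30 months. Ttr, the transthyretin secreted by choroid plexus, stood at 17.5 CPM in replicate 1 of 9 months and at 366 to 870 CPM in the other 24 libraries.

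**Figure D2:**
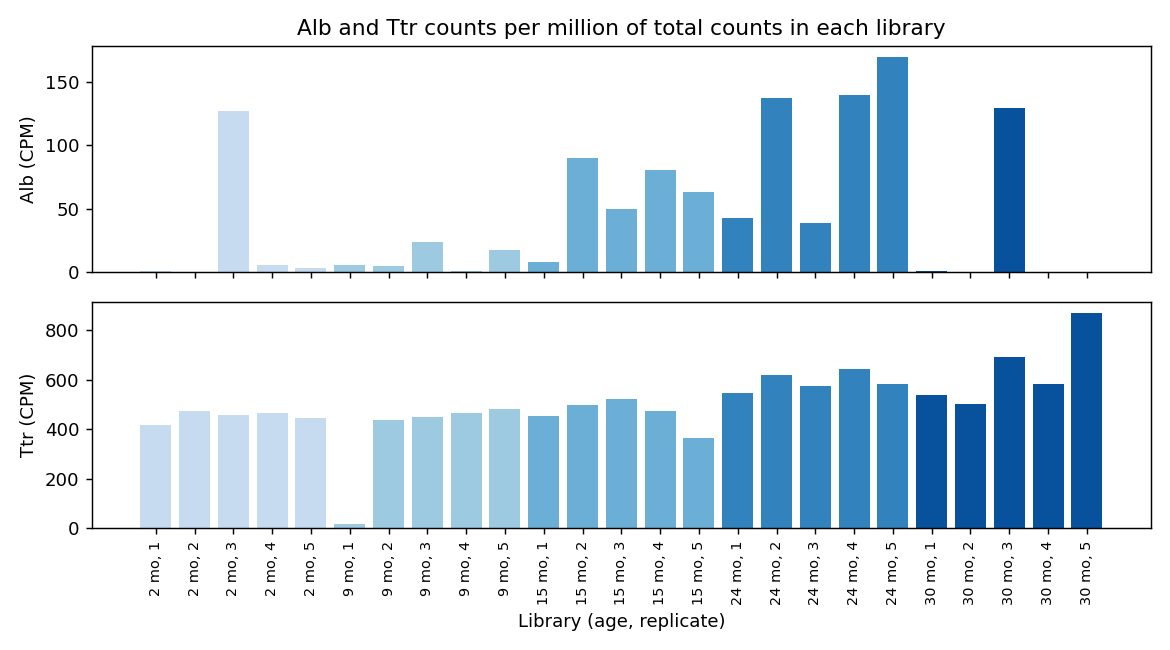
CPM of Alb and of Ttr (y axes, bars from 0) in each of the 25 libraries (x axis, age and replicate), coloured by age. Alb reaches 17.5 CPM or more in 13 libraries, and Ttr is 17.5 CPM in replicate 1 of 9 months.

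From 2 to 9 months, many chaperones rose, and some genes of cell division, immature neurons and vessel walls fell. Hspa1b (ENSMUSG00000090877, GRCm38 chromosome 17, 34956436 to 34959238), an inducible Hsp70 chaperone, rose 2.8-fold from 2.02 ± 0.550 to 5.73 ± 1.46 CPM (SD, n = 5; log2 fold change 1.48, adjusted p = 0.00322). Its near-identical paralog Hspa1a rose by a log2 fold change of 1.18 (adjusted p = 0.0019). The other named rises were Sdf2l1, a protein of the endoplasmic reticulum (log2 fold change 0.92), the lipid transporter Abca8a (0.91), the melanosome transport adaptor Mlph (0.94) and the homeobox gene Six4 (0.74). Pla2g4e, a phospholipase A2, fell from 15.7 ± 1.93 to 7.73 ± 1.03 CPM (SD, n = 5; log2 fold change -1.03, adjusted p = 0.00014). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a clock output transcription factor, fell from 44.9 ± 3.62 to 25.6 ± 2.45 CPM (SD, n = 5; log2 fold change -0.81, adjusted p = 0.000196). The proliferation marker Mki67 (-0.97) and the muscle protein genes Myh3 (-0.85) and Tnni1 (-0.83) fell as well. Members of lists named here and at later ages, beyond the 3 that a rule fixed for each list, are those past the test, chosen after their values were seen.

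Of the 20 genes of the heat shock and unfolded protein response list, 12 rose and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 2.63e-27, and 0.00761 with an estimated correlation). Most were chaperones of the endoplasmic reticulum, among them Hspa5 (log2 fold change 0.72), Pdia4 (0.56) and Calr (0.49). Of 18 immature neuron genes 4 fell and none rose (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.00761 with an estimated correlation), with Nrep at -0.56, Sox4 at -0.40 and Igfbpl1 at -1.02. Of 12 pericyte and smooth muscle genes 5 fell (7 adjusted over the list alone; adjusted p = 0.0184 with an estimated correlation), including the contractile genes Myh11 (-0.61), Tagln (-0.58) and Acta2 (-0.43). Of 15 cell division genes 2 fell (3 adjusted over the list alone; adjusted p = 0.0184 with an estimated correlation). The other 5 lists past the camera test lost their call with an estimated correlation. Of 20 myelin genes 6 fell, such as Mog (-0.54) and Opalin (-0.55) (1 rose and 7 fell adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). Of 15 oligodendrocyte precursor genes 1 fell, Gpr17 (-0.42) (2 adjusted over the list alone; adjusted p = 0.0632 with an estimated correlation), and of 16 collagens 2 fell (5 adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation). Of 21 beta protocadherins, cell adhesion proteins of neurons, 4 rose (5 adjusted over the list alone; adjusted p = 0.618 with an estimated correlation). None of 15 choroid plexus genes passed, and that list's call (adjusted p = 0.917 with an estimated correlation) includes the library with Ttr at 17.5 CPM. In the circadian list Arntl rose (0.32) and Nr1d1 (-0.45), Dbp and Ciart (-0.77) fell (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.657).

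In all, 214 genes rose and 209 fell from 2 to 9 months, 39 and 54 of them by at least 1.5-fold. Scaled by total counts alone, 128 of 384 genes past the test rose and the rest fell. When the 4 libraries of 30 months, whose spread the fit otherwise shares, were left out, 1362 rose and 1178 fell, all 423 of the first count among them in the same direction. Of 423 genes, leaving out 1 library gave 187, 2.5e+02, 230 or 277 (2 months replicates 2, 3, 4 and 5), 241, 233, 226 or 249 (9 months replicates 1 to 4), 850 or 888 (30 months replicates 1 and 5). Mki67 lost its call without 2 months replicate 2, 4 or 5 or any 1 of the 9 month libraries (adjusted p = 0.0765 to 0.143), and Myh3 without 2 months replicates 2 to 5 or 9 months replicates 1 to 4 (0.0506 to 0.0766). The number of lists past camera, 9, became 14 without 2 months replicate 1.

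**Figure D3:**
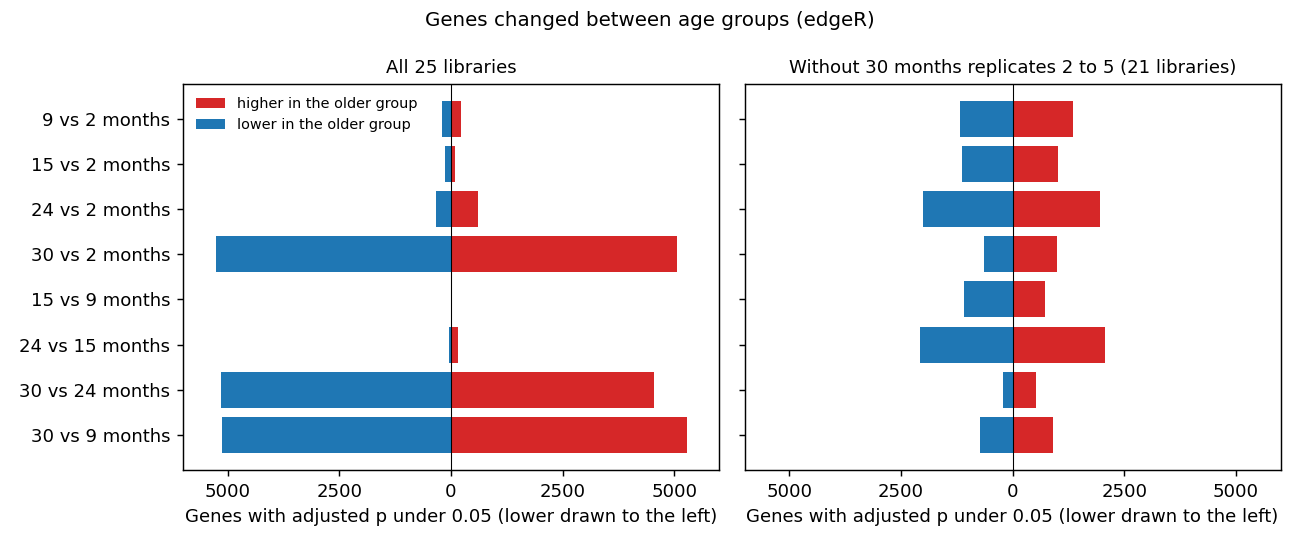
Number of genes past an adjusted p of 0.05 in edgeR, higher (red, right) or lower (blue, left) in the older group, for each pair of ages (y axis), in all 25 libraries and without replicates 2 to 5 of 30 months. The pair 30 and 2 months has 5068 higher and 5256 lower genes in 25 libraries and 997 and 642 in 21.

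At 15 months, complement C4b and the neuronal adhesion gene Pcdhb9 stood about as far above 2 months as Met and Tnnc1 stood below. C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882), a complement component nearly identical to C4a, rose from 23.3 ± 3.30 to 48.0 ± 3.63 CPM (SD, n = 5; log2 fold change 1.04, adjusted p = 0.000917). Pcdhb9 (ENSMUSG00000051242, chromosome 18, 37400855 to 37403909) rose from 11.9 ± 0.511 to 21.2 ± 1.11 CPM (SD, n = 5; log2 fold change 0.83, adjusted p = 1.71e-07). Abca8a (1.20), Mlph (0.95), the flagellar gene Spag6 (0.89) and the collagen Col2a1 (0.83) rose. Met (ENSMUSG00000009376, chromosome 6, 17463800 to 17573980), the receptor of hepatocyte growth factor, fell from 13.1 ± 0.842 to 6.85 ± 0.394 CPM (SD, n = 5; log2 fold change -0.93, adjusted p = 0.000292). Gpr17, a receptor of maturing oligodendrocyte precursors, fell from 64.1 ± 9.83 to 39.2 ± 4.04 CPM (SD, n = 5; log2 fold change -0.71). The troponin gene Tnnc1 (-1.002), the ubiquitin ligase gene Rnf122 (-0.86), Col1a2 (-0.74) and the matrix gene Emid1 (-0.74) fell as well. Col1a2 lost its call with a covariate for liver transcripts (log2 fold change -0.60, adjusted p = 0.0628), and 4 of 5 libraries of 15 months carried Alb at 10 CPM or more.

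The calls of 6 lists held with an estimated correlation. Of 21 beta protocadherins 5 rose and none fell (9 and 0 adjusted over the list alone; adjusted p = 0.0207 with an estimated correlation). Of 18 immature neuron genes 4 fell (9 adjusted over the list alone; adjusted p = 0.000122 with an estimated correlation), and of 15 oligodendrocyte precursor genes 3 fell, Gpr17, Neu4 (-0.52) and Fyn (-0.14) (4 adjusted over the list alone; 0.00483). Cell division had 2 of 15 lower, Top2a (-1.67) and Rrm2 (-1.03) (6 adjusted over the list alone; 0.00822), and pericytes and smooth muscle 5 of 12 (6 adjusted over the list alone; 0.0126). Collagens had 2 of 16 lower (6 adjusted over the list alone; 0.0279). Of 15 genes of MHC class I antigen presentation 3 rose, H2-Q6 (1.78), H2-Q7 (1.77) and H2-T22 (0.46) (13 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation); reads of the H2-Q genes can be shared between these close paralogs. Heat shock had 2 of 20 higher (10 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation), and myelin 6 of 20 lower (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). The call was also lost for complement (1 of 14 higher, also adjusted over the list alone; adjusted p = 0.28 with an estimated correlation) and the interferon response (1 of 23 higher, 3 adjusted over the list alone; adjusted p = 0.346 with an estimated correlation). Glucocorticoid response (0 of 12, 1 lower adjusted over the list alone; adjusted p = 0.346 with an estimated correlation), leptomeningeal fibroblasts (0 of 15, 1 lower adjusted over the list alone; 0.483) and immediate early genes (0 of 14, also adjusted over the list alone; 0.72) lost theirs too. The mean log2 level of the heat shock list relative to 2 months was 0.316 to 0.532 in 15 months replicates 1 to 3. In replicates 4 and 5 it was 0.022 and 0.05, against -0.059 to 0.046 in the 2 month libraries.

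From 2 to 15 months 93 genes rose and 131 fell, 40 and 33 by at least 1.5-fold. DESeq2 called 173 higher and 171 lower, and with RLE size factors 110 rose and 101 fell. The 15 month libraries leaned toward low GC content (gap -0.30 to -0.13), and with a GC correction 180 rose and 208 fell. In the 21 libraries 1024 rose and 1138 fell, with all 224 genes of the first count kept in direction. Of 224 genes, leaving out 1 library gave 117, 106 or 128 (15 months replicates 1 to 3), 130, 140, 133 or 130 (2 months replicates 2 to 5), 550 or 547 (30 months replicates 1 and 5).

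Between 9 and 15 months 3 genes passed. Maged2, a melanoma antigen family gene on the X chromosome, rose from 41.1 ± 2.78 to 50.4 ± 2.26 CPM (SD, n = 5; log2 fold change 0.30, adjusted p = 0.0359). Rxrg, a retinoid X receptor, fell from 21.5 ± 1.05 to 16.6 ± 0.964 CPM (SD, n = 5; log2 fold change -0.37, adjusted p = 0.0402). The predicted gene AC149090.1 rose (0.82, adjusted p = 0.00117) and is named because so few passed, after its values were seen. At an unadjusted p under 0.05 there were 1992 genes; limma-voom called 2 higher and 1 lower, DESeq2 19 and 17, and RLE size factors or total counts alone 2 and 0. Among lists, MHC class I had 0 of 15 past the test over all genes (6 higher adjusted over the list alone; median log2 fold change 0.54) and beta protocadherins 0 of 21 (3 higher adjusted over the list alone; median 0.15). Heat shock had 0 of 20 (2 lower adjusted over the list alone; median -0.17). All 11 lists past camera lost their call with an estimated correlation (adjusted p = 0.428 to 0.886 with an estimated correlation). In the 21 libraries 730 rose and 1093 fell. Leaving out 1 library gave 1 gene (15 months replicates 1, 4 and 5, 24 months replicates 1, 4 and 5, and 9 months replicate 2), 6 or 8 (9 months replicates 4 and 5), 144, 10 or 105 (30 months replicates 1, 4 and 5). Maged2 lost its call without 15 months replicate 1, 3, 4 or 5 or 9 months replicate 2 or 3 (adjusted p = 0.0509 to 0.172), and Rxrg without any 1 library of 15 months or 9 months replicates 1 to 4 (0.0509 to 0.194).

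At 24 months, complement, MHC class I and activated microglia genes stood well above their 2 month levels. C4b rose 4.86-fold to 113 ± 31.2 CPM (SD, n = 5; log2 fold change 2.28, adjusted p = 4.55e-09). The MHC class I genes H2-Q6 (2.17), H2-Q7 (1.99) and H2-Q4 (1.58), the immunoproteasome subunit Psmb9 (1.32) and Abca8a (1.33) rose as well. Gpr17 (ENSMUSG00000052229, chromosome 18, 31942997 to 31949636) fell to 28.5 ± 2.91 CPM (SD, n = 5; log2 fold change -1.17, adjusted p = 9.1e-08). Met (-1.05), Tnnc1 (-0.95), Rnf122 (-0.84) and the fibrillar collagens Col3a1 (-0.999) and Col1a2 (-0.81) fell. All 5 libraries of 24 months carried Alb, at 38.9 to 170 CPM. With a covariate for liver transcripts the log2 fold change of C4b was 2.37 and that of Col3a1 -0.49 (adjusted p = 0.126). The lists, complement among them, were not tested with this covariate.

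Of 14 complement genes 8 rose and none fell (11 and 0 adjusted over the list alone; adjusted p = 0.0104 with an estimated correlation), among them C3 (1.63) and the microglial C1qa (0.60) and C1qc (0.46). Of 15 MHC class I genes 13 rose (14 adjusted over the list alone; adjusted p = 0.0431 with an estimated correlation), such as H2-K1 (1.10), H2-D1 (0.93) and B2m (0.78). Of 19 activated microglia genes 11 rose (13 adjusted over the list alone; adjusted p = 0.0431 with an estimated correlation), led by Cst7 (2.75), Clec7a (2.52) and Itgax (2.33). Beta protocadherins had 8 of 21 higher (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.0452 with an estimated correlation). Immature neuron genes had 5 of 18 lower (7 adjusted over the list alone; 0.00394), with Nrep at -0.78 and Sox11 at -0.44, and cell division 3 of 15 lower (4 adjusted over the list alone; 0.0431). Of 23 interferon response genes 7 rose, such as Gbp2 (1.14) and Bst2 (0.84) (16 adjusted over the list alone; adjusted p = 0.078 with an estimated correlation). Of 16 reactive astrocyte genes 5 rose, such as Serpina3n (1.25) and Gfap (0.82) (7 adjusted over the list alone; adjusted p = 0.078 with an estimated correlation). Lysosome genes had 4 of 20 higher, including the protease gene Ctss (0.58) (8 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation), and cytokines and chemokines 4 of 15, including Cxcl13 (2.52) (6 adjusted over the list alone; adjusted p = 0.189 with an estimated correlation). MHC class II had 3 of 7 higher (4 adjusted over the list alone; adjusted p = 0.353 with an estimated correlation) and lymphocytes 3 of 9, Igkc (2.66), Ccl5 (2.56) and Cd79b (1.36) (5 adjusted over the list alone; adjusted p = 0.413 with an estimated correlation). Cytosolic ribosomal proteins had 4 of 43 higher (6 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation). In the oligodendrocyte precursor list Sox10 (0.26) rose and Gpr17 and Fyn (-0.12) fell (1 and 3 adjusted over the list alone; adjusted p = 0.0944 with an estimated correlation).

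The remaining lists past camera at 24 months had at most 1 gene past the test over all genes. Glutamate receptors and postsynaptic density had 1 of 17 lower (1 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation). Immediate early genes had 1 of 14 lower (3 adjusted over the list alone; adjusted p = 0.476 with an estimated correlation), glutamatergic cortical neurons 1 of 14 lower (1 adjusted over the list alone; 0.474) and pericytes and smooth muscle 1 of 12 lower (1 adjusted over the list alone; 0.396). The mean log2 level of immediate early genes relative to 2 months was -1.003 and -0.85 in 2 months replicates 1 and 2, 0.59 to 0.67 in replicates 3 to 5, -0.95 to 0.10 at 15 months and -0.86 to -0.06 at 24 months. Ependymal cells (0 of 11, also adjusted over the list alone; adjusted p = 0.419 with an estimated correlation) and hypothalamus (0 of 12, also adjusted over the list alone; adjusted p = 0.396 with an estimated correlation) had higher medians, 0.17 and 0.49. With 1 library left out the camera call of several lists ended. This held for lymphocytes without 24 months replicate 1 (adjusted p = 0.137), glutamatergic cortical neurons without 2 months replicate 5 (0.0908) or 24 months replicate 3 (0.0542), and oligodendrocyte precursors without 2 months replicates 2 or 4 or 24 months replicates 2 or 3 (0.0501 to 0.0918). It also held for pericytes without 2 months replicates 1 or 2 or 24 months replicates 1 or 4 (0.0611 to 0.253) and for ependymal cells without 2 months replicates 1 or 5 or 24 months replicates 2, 4 or 5 (0.0581 to 0.123).

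From 2 to 24 months 602 genes rose and 329 fell, 231 and 73 by at least 1.5-fold. The deposited RPKM, most of which are divided by another library's total, gave 1231 higher and 10 lower with a pseudocount of 0.1 and 1316 and 12 with a pseudocount of 1, and the median over all genes was 0.29 and 0.21. The recomputed RPKM gave 666 and 266. With a covariate for liver transcripts 421 rose and 184 fell, with a GC correction 725 and 1301, and without the 4 libraries of 30 months 1956 and 1996. All 931 genes of the first count were in the last one, in the same direction. Of 931 genes, leaving out 1 library gave 612 or 546 (2 months replicates 2 and 5), 580 (24 months replicate 1), 1815 or 1737 (30 months replicates 1 and 5).

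**Figure D4:**
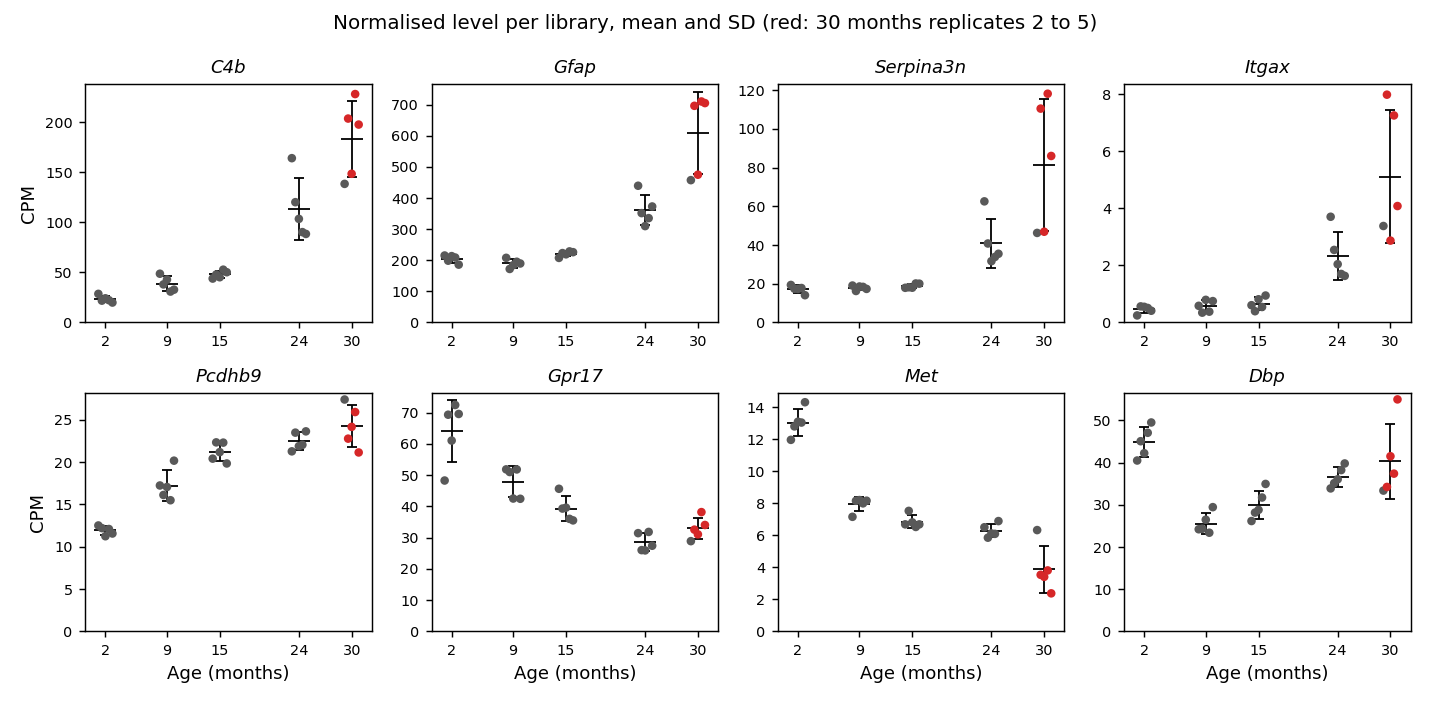
CPM after TMM scaling (y axis) of 8 genes against age in months (x axis), 1 point per library, with group mean and SD (n = 5). C4b climbs from 23.3 CPM at 2 months to 183 CPM at 30 months and Met falls from 13.1 to 3.90, while the red points are replicates 2 to 5 of 30 months.

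Between 15 and 24 months C4b rose from 48.0 ± 3.63 to 113 ± 31.2 CPM (SD, n = 5; log2 fold change 1.24, adjusted p = 0.000719). Serpina3n, a protease inhibitor of reactive astrocytes, rose from 18.8 ± 1.15 to 40.9 ± 12.6 CPM (SD, n = 5; log2 fold change 1.12, adjusted p = 0.0196). Mt2, a metallothionein, rose from 37.8 ± 1.56 to 74.6 ± 8.72 CPM (SD, n = 5; log2 fold change 0.98, adjusted p = 0.00745), and the lipase inhibitor Angptl4 rose as well (1.06). The keratin Krt14 (-0.88), the lactase gene Lct (-0.65), Gpr17 (-0.46) and the adenylate kinase Ak4 (-0.40) fell. Of 19 activated microglia genes 5 rose, Cst7 (1.96), Itgax (1.82), Clec7a (1.41), Csf1 (0.36) and Cd9 (0.35) (14 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). Of 14 complement genes 4 rose (5 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation), of 16 reactive astrocyte genes 3, Serpina3n, Gfap (0.71) and Vim (0.47) (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.252 with an estimated correlation). Of 20 myelin genes 3 rose, Hapln2 (0.51), Trf (0.43) and Mbp (0.32) (10 adjusted over the list alone; adjusted p = 0.252 with an estimated correlation). All 18 lists past camera lost their call with an estimated correlation (adjusted p = 0.158 to 0.583 with an estimated correlation).

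From 15 to 24 months 157 genes rose and 44 fell, 27 and 11 by at least 1.5-fold. DESeq2 called 207 and 185, RLE size factors gave 87 and 62, a GC correction 101 and 213, and the fit without the 4 libraries of 30 months 2063 and 2080. Of 201 genes, leaving out 1 library gave 10, 11, 14, 96 or 79 (15 months replicates 1 to 5), 26, 31, 29, 128 or 54 (24 months replicates 1 to 5), 127, 126 or 107 (2 months replicates 2 to 4), 132 (9 months replicate 5), 951 or 1160 (30 months replicates 1 and 5). Of the named genes, Gpr17, Ak4, Angptl4, Serpina3n and Krt14 lost their call without 15 months replicate 1, 2 or 3, Krt14 also without 15 months replicate 5 (adjusted p = 0.058 to 0.11). They also lost it without some 24 month libraries (0.0563 to 0.0816). These were replicate 1 for Serpina3n, replicates 1 to 3 for Angptl4, 2, 4 and 5 for Krt14, and 1, 2, 3 and 5 for Gpr17 and Ak4.

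From 2 to 30 months C4b rose 7.87-fold to 183 ± 38.3 CPM (SD, n = 5; log2 fold change 2.98, adjusted p = 4.02e-11). Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the astrocyte intermediate filament, rose from 204 ± 12.2 to 609 ± 131 CPM (SD, n = 5; log2 fold change 1.58, adjusted p = 5.66e-10). In replicate 1, the library without the GC trend, C4b stood at 139 CPM and Gfap at 458. Without the other 4 libraries their log2 fold changes were 2.56 and 1.16. Replicate 1 also stood apart from younger libraries. Its mitochondrial ribosomal RNA was 1.56% of counts, against at most 0.847%, and its Malat1 2883 CPM, against at most 920. A shift shared by all 5 libraries of 30 months would therefore remain in values without the 4. Serpina3n rose (2.25, and 1.42 without the 4 libraries), as did the phagocyte genes Gpnmb (1.91, 1.24), Lgals3 (1.90, 1.46), Lyz2 (1.56, 1.14) and Cd52 (1.76, 1.25). The immune checkpoint gene Lag3 (1.57, 1.19), H2-Q4 (1.75, 1.52) and the imprinted noncoding RNA Kcnq1ot1 (1.604, 2.27) rose under both. H2-Q7 (2.20) and H2-Q6 (2.12) rose, and without the 4 libraries did not pass (1.77, adjusted p = 0.108, and 1.87, adjusted p = 0.0785).

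The named falls at 30 months were larger in the 4 libraries with the GC trend than in replicate 1, and all 12 genes have a GC content of 36.3% to 46.6%. Ogn, a small leucine-rich proteoglycan, fell from 16.7 ± 2.32 to 4.07 ± 4.28 CPM (SD, n = 5; log2 fold change -2.02), with 11.6 CPM in replicate 1. The ciliary gene Cep290 fell by a log2 fold change of -1.98 and the chaperone Hsp90aa1 by -1.93. In the 21 libraries these values were -0.49 (adjusted p = 0.0042) and -0.63 (adjusted p = 7.93e-05), and that of Ogn was -0.52 (adjusted p = 0.0513). Zfp40 (-1.94, and -0.47 without the 4), Esf1 (-1.85, -0.40), Zfp850 (-1.85, -0.66) and the condensin gene Smc4 (-1.83, -0.51) passed under both. Slc26a7 (-1.99), Hmgn5 (-1.88), Zfp942 (-1.88), Mki67 (-1.85) and Tex15 (-1.85) passed with all libraries and not without the 4 (adjusted p = 0.0731, 0.267, 0.0914, 0.121 and 0.162).

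Immune and glial lists carried most of the list calls at 30 months, and none of the 9 lists past camera held with an estimated correlation. Counts adjusted over the list alone were equal to those over all genes except where given. Of 19 activated microglia genes 17 rose and 2 fell, with Itgax, an integrin of phagocytes, 11-fold higher (log2 fold change 3.46), Trem2 at 1.09 and Fth1 at 0.90 (camera adjusted p = 5.12e-10; adjusted p = 0.205 with an estimated correlation). Without the 4 libraries 13 rose and none fell, and that list's call held with an estimated correlation (0.0312). Complement had 13 of 14 higher and 1 lower, with C1qc at 1.16 and C1qa at 1.10 (adjusted p = 0.205 with an estimated correlation). All 15 MHC class I genes rose, with H2-D1 at 1.44, Tap2 at 1.02 and B2m at 0.96 (adjusted p = 0.531 with an estimated correlation). Of 20 lysosome genes 17 rose and 2 fell, with Cd68 at 1.18, Ctsz at 0.98 and Laptm5 at 0.73 (adjusted p = 0.205 with an estimated correlation). Of 16 reactive astrocyte genes 11 rose and 2 fell, among them S100a6 at 1.08 (adjusted p = 0.205 with an estimated correlation). Interferon response had 12 of 23 higher and 1 lower, with Lgals3bp at 1.13, Bst2 at 1.05 and Ifi27 at 0.66 (adjusted p = 0.708 with an estimated correlation). Its camera call ended without 30 months replicate 1 (adjusted p = 0.18) or replicate 2 (0.0741). Without the 4 libraries, 5 of 15 measured members each of complement and MHC class I rose, 10 of 20 for lysosome, 5 of 16 for reactive astrocytes and 4 of 23 for interferon response.

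Other glial and immune lists did not pass camera (adjusted p = 0.063 to 0.554). Their counts stand beside 5068 higher and 5256 lower genes among all 17799 tested. Microglia identity had 7 of 14 higher and 4 lower, with Selplg at 0.66, Tmem119 at 0.61 and Cx3cr1 at 0.44. MHC class II had 6 of 7 higher, with H2-Ab1 at 1.20, H2-DMb1 at 1.02 and H2-DMa at 0.48. Lymphocytes had 3 of 9 higher, Ccl5 (2.35), Igkc (2.07) and Igha (1.83). Igkc (adjusted p = 0.0577) and Igha (0.106) lost their calls without 30 months replicate 5, and Igha was at -0.62 without the 4 libraries. Cytokines and chemokines had 7 of 15 higher and 2 lower, with Cxcl10 at 2.08, Cxcl16 at 1.23 and Tlr2 at 1.06. Astrocyte identity had 7 of 15 higher and 4 lower, with Aldoc at 0.50, Sox9 at 0.47 and Aldh1l1 at 0.36 (0.00 without the 4 libraries). Myelin had 11 of 20 higher and 7 lower, with Hapln2 at 1.07, Trf at 0.98 and Myrf at 0.65. Oligodendrocyte precursors had 5 of 15 higher and 8 lower (5 and 9 adjusted over the list alone), with Sox10 at 0.68, Gpr17 at -0.96 and the proteoglycan Vcan at -1.23.

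**Figure D5:**
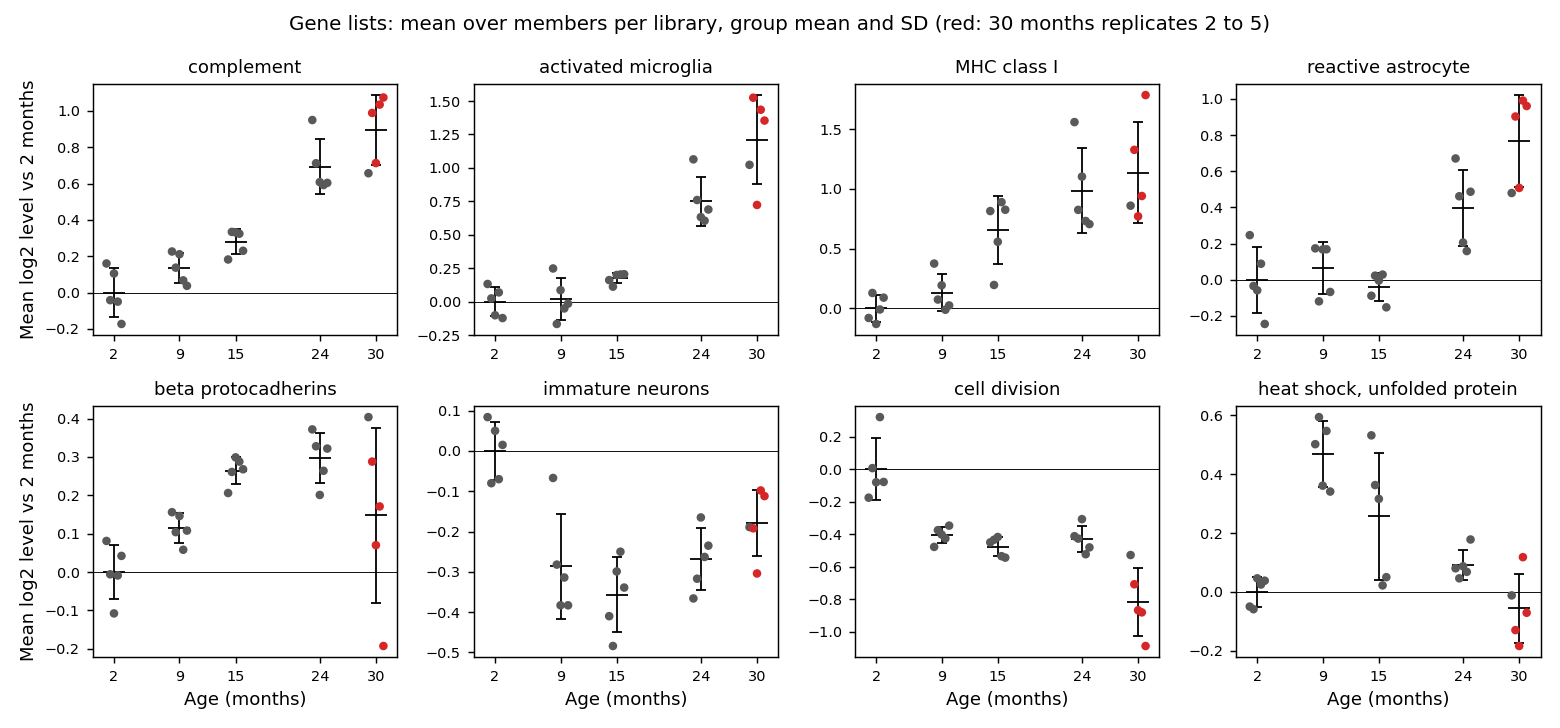
Mean log2 level of the members of 8 gene lists relative to the 2 month mean (y axis) against age in months (x axis), 1 point per library, with group mean and SD (n = 5). Red points are replicates 2 to 5 of 30 months; the activated microglia list reaches 1.02 in replicate 1 of 30 months and 0.61 to 1.06 in the 24 month libraries.

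Neuronal lists moved in both directions at 30 months and did not pass camera, and cell division passed. Of all 17799 genes 5068 rose and 5256 fell, so member counts near these shares do not set a list apart. Of 15 cell division genes 9 fell, with Top2a at -2.11 and Kif11 at -2.09 (adjusted p = 0.205 with an estimated correlation), and the call ended without 30 months replicate 1 (adjusted p = 0.284). The mean log2 level of this list relative to 2 months was -1.087 to -0.707 in replicates 2 to 5. In replicate 1 it was -0.527, within the range of the 9 to 24 month libraries (-0.543 to -0.306). Immature neurons had 3 of 18 higher and 8 lower, with Nrep at -0.61, Dpysl3 at -0.53 and Dcx at -1.39. Glutamatergic cortical neurons had 7 of 14 higher and 3 lower, with Neurod2 at 0.45, Fezf2 at 0.35 and Neurod6 at -0.31, which with a GC correction passed in the other direction (0.32, adjusted p = 0.0199). GABAergic interneurons had 8 of 16 higher and 4 lower, with Htr3a at 0.74, Slc32a1 at 0.60 and Vip at -0.97. Striatal medium spiny neurons had 7 of 15 higher and 3 lower. There Pdyn (0.47), Ppp1r1b (0.39) and Rasd2 (0.30) were at -0.07, -0.12 and -0.09 without the 4 libraries. The presynaptic vesicle cycle had 11 of 18 higher and 6 lower, with Cplx1 at 0.49 and Rab3a at 0.48. Glutamate receptors and postsynaptic density had 4 of 17 higher and 8 lower, with Gria2 at -1.29, Nlgn1 at -0.95 and Grm5 at -0.89, against -0.21, -0.16 and -0.24 without the 4 libraries. Immediate early genes had 1 of 14 lower, Npas4 (-0.68, adjusted p = 0.0387; 0 adjusted over the list alone), while Egr2 (-0.96) and Btg2 (-0.46) did not pass. Npas4 lost its call without 2 months replicate 3, 4 or 5 or 30 months replicate 1, 4 or 5 (adjusted p = 0.0585 to 0.116), while Egr2 passed without 2 months replicate 1 (0.0218) or 2 (0.0291) and Btg2 without 2 months replicate 1 (0.0281). Beta protocadherins had 10 of 21 higher and 8 lower (camera adjusted p = 0.063), with Pcdhb6 at 1.13, Pcdhb9 at 1.03 and Pcdhb3 at 0.77, and without the 4 libraries 8 higher and 0 lower.

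Among lists of metabolism and stress, those of mitochondrially encoded and glycolysis genes passed camera. Member counts here too are to be read against 5068 higher and 5256 lower of all 17799 genes. Of 7 mitochondrially encoded genes 6 fell, with mt-Nd1 at -0.87, mt-Nd4 at -0.82 and mt-Cytb at -0.58 (camera adjusted p = 0.0126; adjusted p = 0.708 with an estimated correlation). The list's median was 0.23 with a GC correction, with mt-Cytb at 0.07, and it did not pass without the 4 libraries (adjusted p = 0.822). Glycolysis had 9 of 15 higher and 1 lower (10 and 1 adjusted over the list alone), with Gapdh at 0.46, Aldoa at 0.44 and Hk1 at 0.29 (camera adjusted p = 0.0486; adjusted p = 0.708 with an estimated correlation). Its median was -0.06 without the 4 libraries, and its call ended without any 1 library of 2 months or 30 months replicates 3 to 5 (adjusted p = 0.0531 to 0.101). Nuclear-encoded oxidative phosphorylation had 17 of 28 higher and 6 lower, with Cox6a1 at 0.69, Ndufs4 at -0.50 (0.03 with a GC correction) and Cycs at -0.93. Cytosolic ribosomal proteins had 20 of 43 higher and 6 lower (21 and 6 adjusted over the list alone), with Rps25 at -0.48 and Rpl4 at -0.68. Heat shock had 6 of 20 higher and 5 lower, with Hsp90aa1 at -1.93, Hsp90b1 at -1.28 and Hsph1 at -0.80, and its mean (-0.02) and median (0.10) differ in sign. Senescence and p53 targets had 8 of 13 higher and 3 lower, with Ccng1 at -1.07 and Trp53inp1 at -1.11. The circadian clock had 7 of 16 higher and 2 lower, with Bhlhe41 at 0.54 and Nr1d2 at -1.11. Glucocorticoid response had 4 of 12 higher and 1 lower, with Mt1 at 0.65 and Arrdc2 at 0.57, at -0.15 and -0.21 without the 4 libraries, and Cables1 at 0.49. Cholesterol synthesis had 8 of 18 higher and 6 lower, with Srebf2 at 0.50 and Fdft1 at 0.49.

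No list of vessels, membranes or neighbouring regions passed camera at 30 months. Counts of members near the shares of all genes (5068 higher and 5256 lower of 17799) do not set a list apart. Collagens had 3 of 16 higher and 7 lower, with Col6a2 at 0.42, Nid1 at -0.35 and Col5a2 at -0.54, and leptomeningeal fibroblasts 5 of 15 higher and 4 lower, with Bmp6 at 0.60 and Slc47a1 at -0.91. Brain endothelium had 3 of 15 higher and 5 lower, with Itm2a at -1.08, Tek at -0.76 and Slco1a4 at -1.57. Pericytes had 2 of 12 higher, Vtn (0.44) and Notch3 (0.25, and -0.07 with a GC correction), and 2 lower, among them Rgs5 (-1.19). Choroid plexus had 1 of 15 higher, Trpv4 (0.57), and 1 lower, Prlr (-1.28), with Kcnj13 at -0.52 not past the test. Ependymal cells had 2 of 11 higher and 2 lower (1 and 2 adjusted over the list alone), with Foxj1 at 0.64, Cfap43 at -0.51 and Tekt1 at -0.53. Red blood cells had 0 of 6, with Hba-a1 at 0.92, Hba-a2 at 0.76 and Slc4a1 at -1.65. Cerebellum had 2 of 12 higher, Cbln1 (0.51) and En2 (0.78), and 1 lower, Itpr1 (-0.38, and 0.06 without the 4 libraries). Cbln1 lost its call without 30 months replicate 4 (adjusted p = 0.0862), and En2 without that library (0.079) or 2 months replicate 1 (0.0528). Hypothalamus had 1 of 12 higher, Avp (1.30), and 2 lower, Pmch (-0.78) and Sim1 (-1.02), which were at 0.04 and 0.13 without the 4 libraries. Sim1 also lost its call without 30 months replicate 3 (adjusted p = 0.0677) or 5 (0.063). Thalamus had 4 of 12 higher and 2 lower, with Tcf7l2 at 0.34, Slc17a6 at -0.79 and Rora at -1.04. Olfactory bulb had 1 of 9 lower, Trhr (-1.54), with Lbhd2 at 0.47 and Nmb at -0.27, and monoamine nuclei 0 of 8, with En1 at 0.57, Ddc at 0.18 and Slc18a2 at -0.51. Pituitary had 2 of 3 lower, Tshb (-1.30) and Gh (-2.24, adjusted p = 0.0498), with Pomc at -0.35. Gh lost its call without 2 months replicates 3 to 5 or 30 months replicates 1, 3, 4 or 5 (adjusted p = 0.0644 to 0.22). With 1 library of 30 months left out, Kcnj13 passed without replicate 1 (adjusted p = 0.0344), Slc18a2 without replicate 1 (0.029) or 2 (0.0303), Hba-a1 (0.0357) and En1 (0.0349) without replicate 3, and Lbhd2 without replicate 4 (0.0335). Nmb passed without 2 months replicate 2 (adjusted p = 0.0387). The mean and median differ in sign for leptomeningeal fibroblasts, endothelium, pericytes, choroid plexus, thalamus and olfactory bulb.

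In all, 5068 genes rose and 5256 fell from 2 to 30 months, 1021 and 2714 of them by at least 1.5-fold (3833 rose and 4267 fell with a GC correction). Without the 4 libraries 997 rose and 642 fell; 1143 genes passed both times, 1109 of them in the same direction.

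Between 24 and 30 months 2 nuclear noncoding RNAs and a mitochondrial ribosomal RNA rose. Kcnq1ot1 rose from 8.17 ± 1.43 to 28.5 ± 12.5 CPM (SD, n = 5; log2 fold change 1.81, and 2.47 without the 4 libraries). Malat1 rose from 790 ± 85.7 to 1919 ± 725 CPM (SD, n = 5; log2 fold change 1.28, and 1.87 without the 4). The mitochondrial ribosomal RNA mt-Rnr1 rose from 2757 ± 136 to 5971 ± 698 CPM (SD, n = 5; log2 fold change 1.12, and 0.84 without the 4). Gpnmb (1.14) rose and did not pass without the 4 libraries (0.47, adjusted p = 0.236). Iigp1, an interferon-inducible GTPase (-2.09), Cep290 (-1.94), Slc26a7 (-1.93) and Ogn (-1.87) fell, and of these Cep290 alone passed without the 4 libraries (-0.45, adjusted p = 0.0122). Of 19 activated microglia genes 16 rose and 2 fell, also adjusted over the list alone. Of 20 lysosome genes 14 rose and 3 fell (15 and 3 adjusted over the list alone), and of 16 reactive astrocyte genes 10 rose and 1 fell, also adjusted over the list alone. Of 18 presynaptic vesicle genes 12 rose and 3 fell, also adjusted over the list alone, and of 7 mitochondrially encoded genes 6 fell (7 adjusted over the list alone). The mean log2 level of the mitochondrially encoded list relative to 2 months was -0.682 to -0.529 in replicates 2 to 5 of 30 months. In replicate 1 it was -0.019, within the range of the 24 month libraries (-0.048 to 0.07). These 5 lists passed camera and lost their call with an estimated correlation (adjusted p = 0.968 with an estimated correlation), and the number was 3 without 24 months replicate 3 or 30 months replicate 1. In all 4543 genes rose and 5158 fell, and without the 4 libraries 530 and 209; of 384 genes that passed both times 365 had the same direction.

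Of the genes that the naming rule picks for 9 and 30 months, C4b had the largest rise. It rose 4.74-fold from 38.6 ± 7.32 to 183 ± 38.3 CPM (SD, n = 5; log2 fold change 2.25, adjusted p = 2.96e-09). Serpina3n (2.19), H2-Q7 (2.04), Lgals3 (1.94), Gpnmb (1.85) and H2-Q6 (1.69) rose, and H2-Q7 and H2-Q6 did not pass without the 4 libraries (adjusted p = 0.135 and 0.166). Ogn (-2.02), Slc26a7 (-2.004), Cep290 (-1.93), Hsp90aa1 (-1.91), Hmgn5 (-1.88) and Zfp942 (-1.86) fell, and of these Slc26a7, Hmgn5 and Zfp942 did not pass without the 4 libraries (adjusted p = 0.0677, 0.234 and 0.105). Of 20 myelin genes 12 rose and 3 fell, also adjusted over the list alone, and of 20 heat shock genes 1 rose and 13 fell, also adjusted over the list alone. Of 19 activated microglia genes 17 rose and 1 fell (17 and 2 adjusted over the list alone). The 9 lists past camera lost their call with an estimated correlation (adjusted p = 0.291 to 0.936 with an estimated correlation). In all 5281 genes rose and 5139 fell, by total counts alone 6743 and 4248, and without the 4 libraries 907 and 733; of 1069 genes that passed both times 1023 had the same direction.

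Across all 5 ages, C4b had the steepest slope of the rising named genes. It rose by 0.106 log2 units per month (adjusted p = 7.07e-13), and by 0.0994 without the 4 libraries. Gfap rose by 0.0576, Lag3 by 0.057, the protocadherin gene Pcdhb6 by 0.0396, the link protein gene Hapln2 by 0.0367 and the actin-bundling gene Espn by 0.0352 log2 units per month. The cathepsin gene Ctss (0.0254), the interferon-inducible Ifi27 (0.0241), the myelin gene Pmp22 (0.0216) and Plekhb1 (0.018) rose more slowly. Met fell by 0.0527 log2 units per month, Gpr17 by 0.0375, the imprint regulator Zfp57 by 0.0318 and the G protein regulator Rgs4 by 0.0224. Pcp4 (-0.02), Shroom2 (-0.0177), Exd2 (-0.0139), Fam160a2 (-0.0125), Ube2g1 (-0.0112) and Parp6 (-0.0093) fell more slowly. With a GC correction the slopes of Exd2 (0.0005), Ube2g1 (0.008) and Parp6 (0.0107) were above 0 and did not pass. Of the 13 lists past camera, complement held with an estimated correlation (12 of 14 higher and 1 lower; 13 and 1 adjusted over the list alone; adjusted p = 0.0293 with an estimated correlation). Activated microglia had 16 of 19 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0732 with an estimated correlation), and MHC class I 15 of 15 higher, also adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). The other 10 had adjusted p = 0.109 to 0.696 with an estimated correlation. In all 4227 genes rose and 4134 fell with age, by total counts alone 5555 and 3461, and without the 4 libraries 1668 and 1453.

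A straight line did not describe the 5 group means of 9160 genes, or of 5516 without the 4 libraries. The 8 with the smallest p were mt-Rnr1, mt-Rnr2, Ppia, Rps25, Chgb, Notch3, Gsn and Tnni1. The mitochondrial ribosomal RNA mt-Rnr1 stood at 2370 ± 152, 2850 ± 336, 2728 ± 244, 2757 ± 136 and 5971 ± 698 CPM at 2, 9, 15, 24 and 30 months (SD, n = 5; adjusted p = 2e-06). The actin-severing gene Gsn stood at 71.6 ± 6.16, 51.6 ± 2.95, 51.5 ± 2.04, 62.3 ± 4.65 and 81.6 ± 11.5 CPM (SD, n = 5; adjusted p = 1.26e-05). Tnni1, a troponin, stood at 4.25 ± 0.349, 2.40 ± 0.246, 2.80 ± 0.468, 4.81 ± 0.376 and 5.10 ± 0.839 CPM (SD, n = 5; adjusted p = 1.57e-05).

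Genes called from 2 to 24 months tended to move the same way from 2 to 30 months. In both, 476 genes rose and 188 fell, against 171.4 and 97.2 for independent lists and at most 1 in either direction over 20 simulations of unchanged groups. In these the 2, 24 and 30 month libraries were all drawn at the mean of the 2 month libraries, and both ages shared the simulated 2 month libraries. At most 5 genes per direction passed for 1 age in these simulations, so their overlap tells little about the shared libraries. The log2 fold changes of the 2 comparisons had r = 0.346, against 0.484 to 0.539 in the simulations, and a covariance of 0.0667, against 0.0217 to 0.0265. With a GC correction 498 rose and 732 fell in both, without the 4 libraries 415 and 396 (101.5 and 66.7 for independent lists), and with both changes 313 and 1242. C4b, Abca8a and Psmb9 rose in both, and Gpr17 and Met (-1.05 and -1.74) fell in both. With the 2 month libraries split between the comparisons, a median of 165 rose and 52 fell in both over 20 splits (range 76 to 257 and 27 to 74). Independent lists gave 21.4 to 88.2 and 9.43 to 57.8 over these splits. In each split both counts lay above the values for independent lists of that same split. The number in the same direction, 664, was 423 without 2 months replicate 5, 438 without 24 months replicate 1, and 1192 or 1118 without 30 months replicate 1 or 5. No relation between changes of early and late life was detected across genes: the log2 fold changes of 9 with 2 and of 30 with 15 months had r = 0.026 (exact permutation p = 0.603, two-sided) and rho = 0.05 (exact permutation p = 0.564), over all labelings of 10 libraries as 2 groups of 5, whose smallest p is 0.00794. Genes are not independent replicates, so the test permuted the libraries. Of the 423 genes called from 2 to 9 months, 48.7% moved the same way from 15 to 30 months (exact permutation p = 0.889). The later change includes the 4 libraries with the GC trend, and without them the share was 38.8%. That value rests on 1 library of 30 months, and the 6 labelings left are too few to test it. With 24 with 15 months as the late pair the share was 32.15% (exact permutation p = 0.325).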

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

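Of the tests here, those of the GC content, older age, liver transcripts and choroid plexus, the splits without 4 of the 30 month libraries and the use of simulations for 15 with 9 months were chosen after the result was seen; that of transcript length, the splits with all 25 libraries in the fit and the search for values far from their group were planned.

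Replicates 2 to 5 of 30 months stood apart from the other 21 libraries, with SDs of log2 ratios to the median library of 0.469 to 0.805 against at most 0.18. GC content explained 51.6% to 57.8% of that variance, and after a GC correction the lowest SD was still 0.326. A smooth trend on the GC content of the longest transcript therefore does not account for all of it. The correction used no other measure of GC content, so GC bias as the whole cause stays open. Loss of long transcripts as the whole cause is argued against. In 4 of 4 libraries the partial correlation was larger in size with GC content (0.651 to 0.715) than with length (-0.348 to -0.117). Older age is open, because 1 of 5 libraries of this age lay within the GC range of the younger ones and the rest did not, and the labels give no batch that could part age from preparation. A difference in library preparation or RNA quality between replicates 1 and 2 to 5 may be part of the cause and was not tested.

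Liver transcripts differed between libraries of one age, with Alb on both sides of 10 CPM in 4 of 5 age groups, which argues against age as the only cause. In the 2 and the 30 month groups, 22 of 22 other liver transcripts were highest in the library with the highest Alb (127 CPM in 2 months replicate 3 and 130 CPM in 30 months replicate 3). In these 2 groups only 1 library had Alb at 10 CPM or more. With 2, 4 and 5 such libraries at 9, 15 and 24 months, 12, 9 and 13 of 22 were highest there in the library with the highest Alb. Carry-over of liver RNA may be the source, at dissection or later. These 2 values of Alb lay far from their groups.

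Choroid plexus transcripts were low in replicate 1 of 9 months, with Ttr at 17.9 CPM after TMM scaling and a list mean of -2.23 relative to 2 months. The median difference of the other members from the rest of the age group was -1.54, against -0.29 as the lowest of the other 24 libraries. All 14 of 14 members other than Ttr lay below, against at most 13 in another library, which argues against a loss of Ttr reads alone. Less choroid plexus in this sample is a candidate explanation. Variation between animals is open, and no biological explanation was tested.

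Other splits of the same libraries, 100 drawn of 126 for each pair, tell whether chance can be excluded for a count. For most counts of genes called it can, with 1 of 100 splits, the real one, reaching the count. This held for 9 with 2 months (423, highest other 4), 15 with 2 (224, highest other 2), 24 with 2 (931, 24), 24 with 15 (201, 0), the trend (8361, 3691) and the departure (9160, 1467). For 15 with 9 months 1 of 100 splits reached 3 (highest other 0). But simulations of unchanged 2, 24 and 30 month groups, made for the overlap and not for this pair, gave up to 4 higher or up to 5 lower. Chance is therefore left open for so few genes. For 30 with 24 months 2 of 100 splits reached 9701, the other with 9748. The highest other splits for 30 months called about as many genes as the real ones and point to a structure of the samples: each exchanged replicate 1 of 30 months for 1 younger library and kept replicates 2 to 5 together. Without these 4 libraries 1 of 100 splits reached 2540 for 9 with 2 months (highest other 166), 3952 for 24 with 2 (819) and 4143 for 24 with 15 (317).

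For the numbers of lists past camera chance cannot be excluded. As many lists were called in 83 of 100 splits for 9 with 2 months (9, highest other 22), 35 for 15 with 2 (14, 19), 23 for 24 with 2 (20, 24) and 77 for 30 with 2 (9, 22). The same held in 32 splits for 15 with 9 (11, 18), 10 for 24 with 15 (18, 21), 90 for 30 with 24 (5, 19), 71 for 30 with 9 (9, 24) and 36 for the trend (13, 25).

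Of 630 groups of 5 libraries, 61 held 1 value far from the other 4 by Dixon's ratio, where chance alone flags about 1 in 20 groups, or 31.5. The values are CPM. In replicate 1 of 30 months these were Ogn 11.6, Cep290 22.04, Zfp40 7.19, Hsp90aa1 128, Hmgn5 3.94, Zfp942 5.48, Esf1 22.8, Zfp850 4.19, Tex15 2.52, Smc4 7.92, Pcp4 75.5 and Ube2g1 62.9, the library without the GC trend. In the other 30 month libraries they were Spag6 4.16 in replicate 2 and Pmp22 46.6 in replicate 5. At 24 months replicate 1 held Pla2g4e 17.1, Mki67 2.67, H2-Q4 8.03, Cd52 4.33, Zfp942 5.68, Iigp1 11.6 and Ctss 103, and replicate 2 held Zfp850 5.34, Tex15 4.09 and Ube2g1 59.0. At 15 months replicate 1 held Esf1 35.8, Ifi27 19.6 and Ppia 26.3, replicate 2 Met 7.53, replicate 4 Fam160a2 92.0 and replicate 5 Rps25 35.7. At 9 months replicate 1 held Met 7.16, H2-Q6 1.64, Plekhb1 402 and Parp6 141, replicate 2 Hspa1a 4.49, and replicate 4 Emid1 2.26 and Esf1 34.7. At 2 months replicate 1 held Rnf122 5.76, Cd52 1.95 and Ctss 75.5, replicate 2 Zfp40 8.52 and Malat1 811, and replicate 3 Esf1 28.2.

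Among list means, as log2 level relative to 2 months, the values far from their group were as follows. Replicate 1 of 2 months held cytokines and chemokines 0.341, striatal neurons 0.205 and glucocorticoid response 0.332, and replicate 3 of 2 months cerebellum 1.18. At 9 months replicate 1 held interferon response 0.177 and olfactory bulb 0.373, and replicate 3 leptomeningeal fibroblasts 0.004. The mitochondrially encoded list was at 0.078 in replicate 1 of 15 months and at -0.019 in replicate 1 of 30 months. At 24 months cytokines and chemokines were at 1.15 in replicate 1 and thalamus at 0.008 in replicate 3. Replicate 5 of 30 months held oxidative phosphorylation 0.247 and ribosomal proteins 0.358. The total of 2 months replicate 3, 31.3 in units of 1 000 000 counts, was also far from its group.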

How the results depend on the processing

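Of the settings here, the GC corrections, the liver covariate and the recomputed RPKM were chosen after the data were seen. So were 24 with 15 months as the late pair and the fits without 4 of the 30 month libraries. The others were planned. For named genes, 3312 values under another setting kept direction and side of the threshold, 342 kept direction and lost the call, 9 gained it and 29 reversed; for lists 67 lost the call, 4 reversed and the others were kept. With 1 library left out, 2508 values of genes were kept, 82 lost and 10 gained the call, and 263 of lists were kept and 27 lost it. Values below stand where a count moved by more than 1.5 times or a direction reversed, and the cause was not tested except where given. DESeq2 called 344 genes for 15 with 2 months, 36 for 15 with 9 and 392 for 24 with 15. With no filter, which tests more genes, edgeR called 2.5e+02 for 9 with 2 months (145 higher and 108 lower), 143 for 15 with 2, 1 for 15 with 9 and 106 for 24 with 15. With only the 2 ages in the fit, 2187, 2350 and 3648 genes passed for 9, 15 and 24 with 2 months, 1878 for 15 with 9, 4453 for 24 with 15, 6366 for 30 with 24 and 6943 for 30 with 9, and the overlap was 2080. These fits leave out other ages' spread. On log2 of months 2068 genes had a trend. The deposited RPKM, most of which are divided by another library's total, gave fewer calls except for 24 with 2 months, with 1241 and 1328 at pseudocounts of 0.1 and 1. With a pseudocount of 0.1 limma called 1 gene for 9 with 2 months, 11 for 15 with 2, 3691 for 30 with 2, 0 for 15 with 9 (903 at an unadjusted p under 0.05), 11 for 24 with 15, 4967 for 30 with 24, 3567 for 30 with 9, 1870 for the trend and 3414 for the departure. With a pseudocount of 1 these were 1, 3, 3386, 0 (854 unadjusted), 26, 4907, 3323, 1677 and 3298. The recomputed RPKM gave 5 for 15 with 9 months. With the liver covariate 605 genes passed for 24 with 2 months, 1 for 15 with 9, and 400 in the overlap. Splitting the 2 month libraries, which leaves fewer samples, gave a median overlap of 214.5. With an estimated correlation the lists past camera were 4, 6, 6 and 0 for 9, 15, 24 and 30 with 2 months, 0 for 15 with 9, 24 with 15, 30 with 24 and 30 with 9, and 1 for the trend. By fry, which compares no list with other genes, they were 9 for 15 with 2 months, 26 for 30 with 2, 0 for 15 with 9, 9 for 24 with 15, 17 for 30 with 24, 19 for 30 with 9 and 20 for the trend. The GC correction gave 900, 388 and 2026 genes for 9, 15 and 24 with 2 months, 22 for 15 with 9, 314 for 24 with 15 and an overlap of 1230. It reversed the mitochondrially encoded list (0.229), Neurod6 (0.321, adjusted p = 0.0199, past the threshold in the other direction), Ndufs4 (0.034), mt-Cytb (0.071) and Notch3 (-0.067) at 30 months and the slopes of Exd2 (0.0005), Parp6 (0.0107) and Ube2g1 (0.008). With length corrected as well, 1051, 476 and 2094 genes passed, 70 for 15 with 9, and the overlap was 1221. Exd2 (0.0027), Parp6 (0.009), Ube2g1 (0.0063), Neurod6 (0.223) and Ppp1r1b (-0.010) were reversed. Without 4 of the 30 month libraries the lone library of 30 months is assumed to vary like the other groups. Then 2540, 2162, 3952 and 1639 genes passed for 9, 15, 24 and 30 with 2 months, 1823 for 15 with 9, 4143 for 24 with 15, 739 for 30 with 24, 1640 for 30 with 9, 3121 for the trend and 5516 for the departure. Lists past camera were 18 for 30 with 2 months, 15 for 30 with 9 and 22 for the trend. Reversed at 30 months were glycolysis (-0.063), Igha (-0.621), Pdyn (-0.069), Rasd2 (-0.086), Ppp1r1b (-0.119), Mt1 (-0.146), Arrdc2 (-0.212), Itpr1 (0.063), Pmch (0.036) and Sim1 (0.129). With an estimated correlation as well, 1, 2, 5 and 1 lists passed for 9, 15, 24 and 30 with 2 months, 0 for 15 with 9, 24 with 15 and 30 with 24, 1 for 30 with 9 and 5 for the trend. With the GC correction as well, 2714, 1327, 4425 and 3296 genes passed for 9, 15, 24 and 30 with 2 months, 1352 for 15 with 9, 2413 for 24 with 15, 1731 for 30 with 24, 3863 for 30 with 9, 4608 for the trend and 4924 for the departure. The overlap was then 1555, and lists were 2 for 30 with 24, 15 for 30 with 9 and 22 for the trend. Glycolysis (-0.099), Igha (-0.665), Aldh1l1 (-0.034), Pdyn (-0.115), Rasd2 (-0.122), Ppp1r1b (-0.195), Mt1 (-0.188), Arrdc2 (-0.268) and Itpr1 (0.003) were reversed. With 1 library left out, counts of genes ranged from 187 to 888 (9 with 2 months), 106 to 550 (15 with 2), 546 to 1815 (24 with 2), 9259 to 11607 (30 with 2), 1 to 144 (15 with 9), 10 to 1160 (24 with 15), 8617 to 11310 (30 with 24), 9188 to 11749 (30 with 9), 6522 to 9023 (trend) and 8177 to 11266 (departure). The lowest of these came without 2 months replicate 2 for 9 with 2, 15 months replicate 2 for 15 with 2, 2 months replicate 5 for 24 with 2 and 15 months replicate 1 for 24 with 15, and the highest for these 4 without 30 months replicate 1 or 5. Lists ranged from 7 to 14 (9 with 2 months; 14 without 2 months replicate 1), 13 to 16, 17 to 23, 7 to 11, 8 to 12, 17 to 20, 3 to 6 (30 with 24; 3 without 24 months replicate 3 or 30 months replicate 1), 7 to 11 and 12 to 14 in the order of the gene counts. The overlap ranged from 423 to 1192, without 2 months replicate 5 and 30 months replicate 1, and the correlation of early and late changes from -0.017 to 0.046. The correlation was -0.07 with 24 with 15 months as the late pair (exact permutation p = 0.230). Depth limits the listed genes near the filter: 9 of 19 lymphocyte genes and 3 of 8 pituitary genes were measured.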

Other observations

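No test stands in this part, and its values were picked after they were seen. Mitochondrial messenger RNA took 2.09% to 2.32% of counts in replicates 2 to 5 of 30 months and 3.02% to 3.58% in the other 21 libraries. Malat1, a nuclear noncoding RNA, stood at 961 to 2883 CPM at 30 months, highest in replicate 1, and at 589 to 920 CPM in the 20 younger libraries. Kcnq1ot1 stood at 45.6, 34.8, 24.5, 25.5 and 12.2 CPM in replicates 1 to 5 of 30 months and at 6.47 to 11.4 CPM in the younger libraries. Gh, pituitary growth hormone, reached 6.85 CPM in a 2 month library and 3.29 CPM in a 24 month library.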
